A study of Arabidopsis thaliana with 24 samples.

How the data were processed

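Poly(A) RNA from whole Arabidopsis seedlings, 9 days old and grown in continuous white light, was sequenced in 24 libraries of 8 genotypes with 3 replicates each. The genotypes per the labels were Col-0 WT, hid1, bte1, the bte1 hid1 double, the hid1 phil1 double (its columns carry the name 475A2, and its genotype was taken from the sample characteristics), btl1, the bte1 btl1 double and the e2fa e2fb e2fc triple, here called e2f. Per the submitters' processing notes, TruSeq libraries were sequenced on an Illumina instrument, trimmed with fastp, aligned to TAIR10 with HISAT2 2.1.0 and handled with SAMtools 1.6. The counting tool and the strand it used were not stated. The deposited count table holds raw whole-number counts made by the authors for 33612 features. The deposited FPKM table, whose unit is given per the file headers, holds values per kilobase and scaled by library made by the authors for 55721 features, of which 22109 are assembled loci. Those loci have values in the 15 libraries of WT, hid1, bte1, bte1 hid1 and hid1 phil1 and none in the 9 others, so the FPKM values of the 2 sets cover different features and were not compared across sets. Between replicates the assembled loci had rank correlations of 0.0088 to 0.0593, against 0.984 to 0.989 for annotated features, and they were not used.

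Counts were the main measurement. Total counted reads ran from 14309396 to 23912716 per library, with WT at 22544462 to 23912716, btl1 and bte1 btl1 at 14309396 to 15424866 and e2f at 21270487 to 21885875. Gene names came from TAIR10.1 (32843 features matched, 10658 with a symbol). No coordinates are given, since the alignments used TAIR10. The authors' alignments were not repeated, because no reads were at hand.

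Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM factors (0.922 to 1.03), the filterByExpr filter by genotype (21897 genes tested, 11715 features removed), 1 one-way fit on all 24 libraries with robust quasi-likelihood dispersions, and quasi-likelihood F tests with Benjamini-Hochberg adjustment within each comparison at 0.05. There were 11 pairwise comparisons and 2 tests of non-additivity, which ask whether the log2 change with bte1 differs between the WT and hid1 or between the WT and btl1 backgrounds. The e2f mutant was also tested against btl1 and bte1 btl1, chosen after the library sets were seen. A called gene is one with an adjusted p under 0.05, and CPM are reads scaled by TMM-adjusted library size, except that the summed values of small RNA, seed storage and other seed genes are scaled by total counted reads. The biological coefficient of variation was 0.106.

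Gene lists were tested with camera (limma 3.58.1) with the preset correlation of 0.01, over 19 lists and 11 comparisons (209 tests adjusted together); the lists under the tests of non-additivity were adjusted as a family of their own. The lists were DNA replication, replicative histones, mitosis and cytokinesis, DNA damage response and repair, DNA methylation machinery, DREAM complex and E2F family, H3K4 methylation, cell cycle inhibitors, photosynthesis and chlorophyll, light signalling, flavonoid and anthocyanin, salicylic acid defence, jasmonate and wounding, heat shock, seed maturation, flowering time and floral identity, circadian clock, root cell types and shoot meristem. They held 282 members, of which SOL2 was dropped because the reference gives its symbol to another locus, and 271 were tested. Of the 70 list calls with the preset, 13 held with a correlation estimated from the data.

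The lists, the fits, the alternatives and the rule for named genes were chosen before the data were examined. By that rule each pairwise comparison names the DREAM and E2F family, HID1 and HIL1 whatever their values. It also names the 6 genes with the highest and the 6 with the lowest log2 change among called genes that have a symbol, at least 1 CPM in the higher genotype and libraries that do not overlap. From each list it names up to 3 called members with the smallest adjusted p, and for non-additivity the 5 genes with the smallest adjusted p. Outside hid1, bte1 btl1 and e2f against WT some of these were counted and not named. The values of 1 gene that the rule names are not reported here. Where a group had no read, the fold is a bound against a floor of 3 reads over the group; with 1 to 3 reads a ratio with its 95% counting interval is given.

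Simulated data had the depth and dispersion of these libraries and 200 changed genes, all drawn from genes at about 1 CPM or more in WT. The hid1 against WT test recovered 58.2%, 82.1% and 98.5% of those changed 1.5-fold, 2-fold and 4-fold, and 2.45% of its calls were unchanged genes. The test of non-additivity of bte1 and hid1 recovered 35.8%, 61.2% and 95.5%. Recovery of changed genes with lower counts was not tested. Overlaps between comparisons that share libraries were set against 20 simulations.

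Alternatives were RLE factors, no low-count filter, DESeq2 1.42.0, only the genotypes compared, a replicate block, limma on log2 FPKM within a library set with 1 or 0.1 added, camera with an estimated correlation, fry, and leaving out each library in turn. Added after seeing the data were protein-coding genes only, a fit within 1 library set, and btl1 or bte1 btl1 in place of WT. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.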

Results

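The comparisons asked how the transcripts of seedlings mutated in HID1 (a noncoding RNA gene of light responses), in bte1, in btl1 or in 3 E2F genes differ, and how gene sets tied to the DREAM cell-cycle repressor complex and to H3K4 methylation behave in them. Each of the 8 genotypes had 3 libraries, which per the labels are separate samples. HID1 was at 8.61 CPM (reads scaled to a common library size, SD 1.54, n = 3) in WT and had no read in any of the 3 hid1 or the 3 bte1 hid1 libraries, at least 187-fold and at least 197-fold below WT against a floor of 3 reads over the group. In hid1 phil1 it had 0, 9 and 0 reads in replicates 1, 2 and 3, a mean of 0.14 CPM. The other genotypes kept HID1 at 5.10 to 7.01 CPM, and none of them was called different from WT. In the libraries labelled as the e2fa e2fb e2fc triple mutant, E2FA was at 31.3 CPM against 8.83 in WT, E2FC at 47.5 against 11.6, and E2FB at 5.54 against 6.85. Gene-level counts therefore give no check of that genotype, and BTE1, BTL1 and PHIL1 carry no such name in the reference. Floors and counting intervals here cover counting error only.

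HIL1 rose in every genotype in which bte1 or hid1 was mutated, and in the e2f triple mutant. Its mean was 0.81 CPM in WT (SD 0.0879), 3.88 in hid1 (SD 0.308), 9.18 in bte1 (SD 1.31), 20.4 in bte1 hid1 (SD 2.21) and 27.9 in hid1 phil1 (SD 2.65), with no overlap between these libraries and WT. The log2 changes against WT were 2.25 in hid1 (SE 0.18, adjusted p = 1.65e-08), 3.49 in bte1, 4.64 in bte1 hid1 and 5.09 in hid1 phil1. In the btl1 background HIL1 was at 0.74 CPM in btl1 and 7.99 in bte1 btl1, a log2 change of 3.42 between them. The pseudogene AT2G35743 had nearly the same values in WT (0.87 CPM), hid1 (3.88), bte1 (9.60), bte1 hid1 (21.1) and hid1 phil1 (28.5). It had lower ones than HIL1 in btl1 (0.15), bte1 btl1 (3.525) and e2f (0.93 against 2.30), so the difference followed the 2 library sets. HID1 and HIL1 are named in the count table but not placed in the reference, and the counting strand was not stated, so whether they share reads with such genes was not checked. All adjusted p values come from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment over 21897 genes, unless a list test is named.

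**Figure D1:**
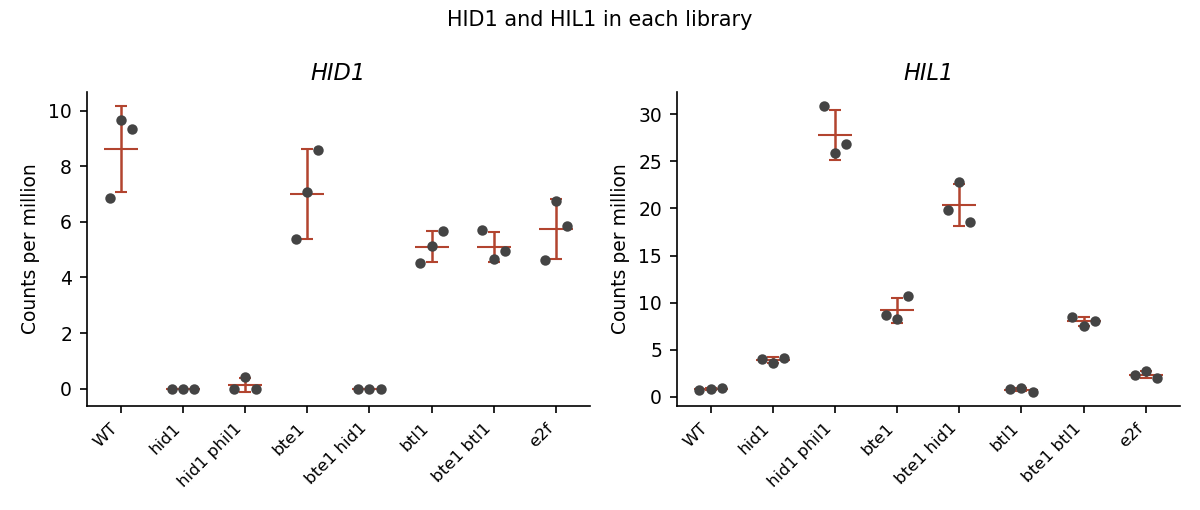
HID1 and HIL1 in CPM for each of the 24 libraries, grouped by genotype; points are libraries, the bar is the mean and the whisker 1 SD (n = 3). HID1 has no read in hid1 and bte1 hid1, and HIL1 has means of 0.81 in WT, 9.18 in bte1, 20.4 in bte1 hid1 and 27.9 in hid1 phil1.

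In hid1 seedlings, genes of mitosis and of the DNA damage response were raised together. HIK, a cytokinesis kinesin, rose by 0.62 on the log2 scale, CDC20.1, an activator of the anaphase ubiquitin ligase, by 0.63, and the mitotic cyclin CYCB1;1 by 0.90, from 6.89 to 12.9 CPM. GMI1, a DNA repair gene, rose from 9.45 to 28.7 CPM (log2 1.602, SE 0.12), RPA1E, a single-strand DNA binding protein, by 1.01, and RAD54, a recombination protein, by 0.64. NAC044, a transcription factor of the DNA damage response, rose by 3.49 (adjusted p = 6.16e-10). Among genes with a symbol, at least 1 CPM and libraries that do not overlap, the others with the largest rises were RE2 (5.02), QQS, a regulator of starch (4.53; 1.53 to 35.1 CPM), the retroelement SADHU3-2 (4.04), the nitrate transporter NRT2.1 (2.91) and SRO3 (2.80). After HID1, the largest falls among genes of this kind were RL1 (-4.05), the MADS-box gene AGL42 (-2.93), RLP18 (-2.53), CYP71B22 (-1.98) and MRD1 (-1.92). MRD1 and HEI10, a meiotic recombination gene that overlaps it on the other strand, went from 29.1 to 7.76 and from 33.5 to 10.1 CPM, and an overlap of this kind leaves open which of them changed. Of the 23 DREAM and E2F genes only SOL1 was called (0.47, SE 0.13, adjusted p = 0.0345); E2FA, E2FB, E2FC and RBR1 had log2 values of 0.04, -0.08, 0.08 and 0.02.

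In hid1 against WT, 378 genes were higher and 376 lower, 115 and 82 of them by at least 2-fold. The libraries of the genotypes did not overlap for 5518 genes, where chance gives 10%, and each gene named for the size of its change was of this kind. The count was 370 without WT replicate 2, 441 without WT replicate 3, 412 without hid1 replicate 1 and 349 without hid1 replicate 3. Leaving out 1 library at a time ended the calls of SOL1 (0.156 without WT replicate 2, 0.17 without WT replicate 3, 0.0897 without hid1 replicate 1, 0.193 without hid1 replicate 3), MET1 (0.0575 without WT replicate 2), NRT2.1, RNR1, MCM5, HTR9, HTR1, VIM1, CMT3, PAP1, JAZ5, HSP70, CCA1 and LHY. CCA1 and LHY lost theirs without any 1 of the 6 libraries.

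Among the gene lists in hid1 against WT, the mitosis and cytokinesis list was higher, with 12 of 25 measured members called higher, 21 when adjusted over the list alone, and a median log2 of 0.48 (camera with a preset correlation, adjusted p = 1.68e-21, adjusted p = 0.0309 with an estimated correlation). For the other lists the first p in a bracket is likewise the adjusted camera p with the preset. In the DNA damage response and repair list 6 of 16 members rose, also 6 adjusted over the list alone, with a median of 0.24 (9.75e-10, adjusted p = 0.0149 with an estimated correlation). Only 2 of 24 DNA replication genes passed, RNR1 (0.33) and MCM5 (0.32), and 12 did adjusted over the list alone; the list was higher with a preset correlation (3.20e-08) but had an adjusted p = 0.185 with an estimated correlation. HTR9 (0.36) and HTR1 (0.30) were the 2 of 18 replicative histones called (list 0.00638, adjusted p = 0.608 with an estimated correlation). Of 11 DNA methylation genes, the methyltransferases MET1 (0.32) and CMT3 (0.42) and the cofactor VIM1 (0.44) rose while the demethylase ROS1 fell by 0.41 (list 0.0415, adjusted p = 0.35 with an estimated correlation). The light signalling list was lower, with PIF5, a phytochrome-interacting factor, as the 1 called member of 17 (-0.65; 0.00383, adjusted p = 0.175 with an estimated correlation). The jasmonate list had JAZ5 (1.23) called of 10 (0.0473, adjusted p = 0.524 with an estimated correlation). No seed maturation gene of 12 and no flowering gene of 13 was called at an adjusted p below the threshold, although both lists passed with the preset (0.0139 and 0.0105, adjusted p = 0.637 and 0.192 with an estimated correlation). Summed seed storage reads were at 1.04, 87.0 and 12.8 CPM in hid1 replicates 1, 2 and 3, against at most 0.83 in WT.

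The remaining lists were not called in hid1. PAP1, an activator of anthocyanin synthesis, was at 2.05 as 1 of 11 flavonoid genes, HSP70 at 0.32 as 1 of 5 heat shock genes, and NRT2.1 was 1 of 10 root cell type genes, a list with a median of -0.19, a mean of 0.12 and a test pointing down (0.364). The clock genes RVE8 (-0.63), CCA1 (-0.69) and LHY (-0.60) fell among 12, without a call for the list (0.173). No gene was called among 12 H3K4 methylation, 10 cell cycle inhibitor, 22 photosynthesis, 13 salicylic acid or 7 shoot meristem genes. List calls were lost without 1 library for histones (0.103 without WT replicate 2, 0.0724 without hid1 replicate 1), DNA methylation (0.088 without WT replicate 2, 0.0723 without WT replicate 3, 0.0517 without hid1 replicate 2, 0.0653 without hid1 replicate 3), jasmonate (0.156 without WT replicate 1, 0.131 without hid1 replicate 1), seed maturation (0.0797 without WT replicate 1, 0.223 without hid1 replicate 2) and flowering (0.0597 without hid1 replicate 3). The preset correlation is lenient here: other groupings of the same 6 libraries gave up to 10 list calls where the real one gave 9.

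In hid1 phil1 seedlings most of the genes changed in hid1 moved back towards their WT levels. Of the 754 genes called in hid1, 481 (63.8%) were called in the opposite direction between hid1 phil1 and hid1, 5 in the same direction and 268 not at all. The medians of the genes higher and lower in hid1 were 0.61 and -0.61 there and 0.09 and -0.07 in hid1 phil1 against WT. In 20 simulations where hid1 phil1 had the levels of hid1, at most 1 gene was opposed. These simulations took the fitted means as true levels and called a mean of 1883 genes in hid1, more than the 754 of the data. With no change set between hid1 phil1 and hid1, they cannot show what the shared hid1 libraries add among changed genes. QQS fell by 5.62 against hid1, RE2 by 5.58, SADHU3-2 by 4.03, NAC044 by 3.22 and SRO3 by 3.12, while AGL42 rose by 2.69. Mitosis genes fell (13 of 25, 21 adjusted over the list alone; median -0.43; 2.16e-14, adjusted p = 0.0882 with an estimated correlation), as did 8 of 16 DNA damage genes, among them GMI1 (-1.74) and RPA1E (-1.04; list adjusted p = 0.00767 with an estimated correlation). DNA replication was lower with the preset only (6 of 24, 15 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation), and photosynthesis (1 of 22) and root cell types (4 of 10) were higher with the preset only (adjusted p = 0.698 and 0.175 with an estimated correlation). The photosynthesis call ended without hid1 phil1 replicate 2 (0.641).

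Between hid1 phil1 and hid1, 774 genes were higher and 639 lower. This count of 1413 was 865, 920 and 460 without hid1 replicate 1, 2 and 3, and 682 and 878 without hid1 phil1 replicate 2 and 3. Replicate 2 of hid1 phil1 stood apart from the others over the genes as a whole. The spread of counts, as chi-square per degree of freedom, was 20.4 and 20.8 between it and replicates 1 and 3. Between those it was 4.76. The e2f replicates also lay far apart, at 15.76 (1 and 2), 34.38 (1 and 3) and 22.95 (2 and 3). The 481 opposed genes became 282 without WT replicate 2, 288 without WT replicate 3, 277 without hid1 replicate 1 and 198 without hid1 replicate 3. DEL3 (-0.67), an E2F-like repressor, and SOL1 (-0.42) were the DREAM and E2F genes called, and neither call held in every fit that left out 1 library. DEL3 went to 0.0858 without hid1 replicate 3 and 0.093 without hid1 phil1 replicate 2; SOL1 went to 0.23 without hid1 replicate 3 and lost its call without each of the other libraries but hid1 replicate 2.

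Against WT, hid1 phil1 had 11 genes higher and 14 lower, and the genes changed most included HID1, HIL1, MRD1 and a run of adjacent genes. HID1 was lower by 5.90 on the log2 scale, the adjacent genes AT2G35744 (a snoRNA gene), AT2G35750 and AT2G35747, which had no read in hid1 either, by 5.76, 6.12 and 7.30, MRD1 by 5.55 and HEI10 by 4.14. AT2G35744 and AT2G35747 also had at most 4 reads in each of btl1, bte1 btl1 and e2f, where HID1 and AT2G35750 were kept. AT2G35760, the next gene in TAIR10.1, was higher by 1.99, and it was also at 33.8 CPM in hid1 and 31.3 in bte1 hid1 against 9.22 in WT. AT1G19115 was higher by 4.60 while its neighbour LSM1A, a decapping cofactor, was at -1.01. The transposon-type entry AT5G43800.1 had 309 reads in WT, 4 in hid1 and 0 in hid1 phil1 and in each of the other 5 genotypes. The genes named here by locus were chosen after their values were seen. The calls of RAP2.4 (0.42), EMB1444 (0.41), ABCG22 (0.37), PRXCA (-0.65), AT1G06149, AT2G16245 and AT5G43800.1 were lost without 1 or more libraries. Histones, jasmonate and root cell types were higher as lists with no member called (0.0105, 0.0232 and 8.44e-05, adjusted p = 0.63, 0.442 and 0.144 with an estimated correlation). The histone call ended without WT replicate 2 (0.261), WT replicate 3 (0.108) and hid1 phil1 replicate 2 (0.716), and the jasmonate call without WT replicate 1 (0.143) and hid1 phil1 replicate 2 (0.187). Unadjusted, 1516 genes had p under 0.05, and a simulation with no changed gene gave 0 calls.

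In bte1 seedlings, HAF2, NUC-L2 and TAF4B were among the genes with a symbol that rose most. HAF2, a TAF1-type histone acetyltransferase, rose from 1.27 to 19.6 CPM (log2 3.95, SE 0.19, adjusted p = 2.13e-13), TAF4B, a component of the general factor TFIID, by 2.52, and the nucleolin gene NUC-L2 from 1.69 to 11.3 CPM (2.74). SBT3.3, a subtilase, rose by 2.71 and RABH1a by 2.54. The H3K4 methyltransferase ATX1 rose by 1.03, the DNA ligase LIG1 by 0.69, the replication licensing factor CDT1A by 0.42, the origin subunit ORC3 by 0.60, CMT3 by 0.64 and HSP70 by 1.75. Among DREAM and E2F genes RBR1, the retinoblastoma homolog, rose by 0.38, E2FA by 0.55 and TCX6 by 0.75. Among genes with a symbol, at least 1 CPM and libraries that do not overlap, the largest falls were those of OSM34 (-1.85), RLP18 (-1.83), the cold regulator DREB1A (-1.64), UGT85A2 (-1.62), the cold-induced COR15B (-1.47) and GDPD6 (-1.43). In the defence list ICS1, of salicylic acid synthesis, rose by 0.43, and MAF4, a floral repressor, and STM, a meristem gene, fell by 0.85 and 0.80.

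In all, 413 genes were higher and 138 lower in bte1, and 4831 had libraries that did not overlap, where chance gives 10%. Without WT replicate 3, bte1 replicate 1 and bte1 replicate 3 the 551 became 338, 358 and 334. Single libraries decided the calls of E2FA (0.0677 without bte1 replicate 3), TCX6 (0.18 without WT replicate 3, 0.251 without bte1 replicate 3), SBT3.3, OSM34, DREB1A, COR15B, GDPD6, CDT1A, ORC3, ICS1, MAF4 and STM. The heat shock list was higher (2 of 5 called; median 0.67, adjusted p = 0.00033 with an estimated correlation). DNA replication was higher with the preset only (5 of 24, 7 adjusted over the list alone; 0.000138, adjusted p = 0.378 with an estimated correlation), as were histones with no member called (0.0335, adjusted p = 0.704 with an estimated correlation). Photosynthesis (0 of 22, median -0.25), flowering (MAF4) and shoot meristem (STM) were lower with the preset only (adjusted p = 0.508, 0.193 and 0.378 with an estimated correlation). The histone call ended without WT replicate 2 (0.333), WT replicate 3 (0.11), bte1 replicate 1 (0.0674) and bte1 replicate 3 (0.0862), and that of shoot meristem without WT replicate 3 (0.216), bte1 replicate 2 (0.118) and bte1 replicate 3 (0.08). DREAM and E2F genes had 3 of 23 called, a median of -0.003, a mean of 0.03 and no list call (0.335). Mitosis (0 of 25) and DNA damage (0 of 16) had no called member.

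In the bte1 hid1 double mutant most of the genes higher in bte1 stayed high and much of the hid1 response was smaller. Against WT, HAF2 was higher by 4.096, NUC-L2 by 3.26, RABH1a by 2.72, ATX1 by 1.098, HSP70 by 1.72, E2FA by 0.66 and RBR1 by 0.39, and of the genes higher and lower in bte1, 300 and 29 were called alike. Part of that overlap may come from the shared WT libraries. Independent lists would share 8.19 and 0.58, and the covariance was 0.0984 against 0.0252 simulated. Simulated genotypes without a change shared 0, which cannot show what shared libraries add among changed genes. SADHU3-2 (3.96) and QQS (3.48; 16.9 CPM) were still high, and MRD1 (-1.92) and HEI10 (-1.83) still low. Of the 754 hid1 genes 391 (51.9%) were opposed between bte1 hid1 and hid1, 9 went the same way and 354 were not called. The same simulations, with the double mutant at the levels of hid1, had at most 1 opposed. With no change set between the double mutant and hid1, they cannot show what the shared hid1 libraries add among changed genes. The medians of the hid1 genes against WT went from 0.61 to 0.14 for the higher and from -0.61 to -0.19 for the lower genes. Against hid1, HIK fell by 0.64, GMI1 by 0.94, RPA1E by 1.03, BRCA1 by 0.74, GH9B15 by 3.17 and RE2 by 2.61, while HAF2 rose by 3.45 and RPA, the root and pollen ARFGAP gene, by 3.30. Of 25 mitosis genes 14 fell, 21 adjusted over the list alone (median -0.47; 1.72e-15, adjusted p = 0.0687 with an estimated correlation), and the list had a p of 0.997 against WT with no member called.

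Against WT, bte1 hid1 had 434 genes higher and 92 lower; against hid1, 948 higher and 680 lower. The 1628 became 814 without hid1 replicate 3 and 891 without bte1 hid1 replicate 1. The 391 opposed genes became 221 without WT replicate 2, 245 without WT replicate 3, 213 without hid1 replicate 1, 159 without hid1 replicate 3 and 252 without bte1 hid1 replicate 1. With the preset, 4 lists were higher and 2 lower against WT, and 2 were higher and 6 lower against hid1. Heat shock was higher against WT and against hid1 (adjusted p = 0.000561 and 0.0368 with an estimated correlation). The other lists called with the preset were lost with the estimate. Against WT these were DNA replication (3 of 24, adjusted p = 0.37 with an estimated correlation), H3K4 methylation (2 of 12; 0.234), photosynthesis (0 of 22; 0.378), flavonoids (0 of 11; 0.758) and root cell types (0 of 10; 0.35). Against hid1 these were DNA damage (4 of 16 lower, adjusted p = 0.0962 with an estimated correlation), histones (2 of 18; 0.63), photosynthesis (0 of 22; 0.704), flavonoids (0 of 11, 5 adjusted over the list alone; 0.54), seed maturation (0 of 12; 0.63) and root cell types (5 of 10 higher, 1 lower; 0.234). Without 1 library the calls of H3K4 methylation (0.0579 without WT replicate 1, 0.121 without WT replicate 3, 0.167 without bte1 hid1 replicate 2), flavonoids (0.114 without WT replicate 1, 0.307 without WT replicate 3, 0.424 without bte1 hid1 replicate 1) and root cell types (0.0558 without bte1 hid1 replicate 3) against WT ended, and so did those of histones (0.0831 without hid1 replicate 1, 0.0523 without bte1 hid1 replicate 2), photosynthesis (0.0606 without bte1 hid1 replicate 2) and seed maturation (0.132 without hid1 replicate 2) against hid1. SOL1 (-0.46) and MYB3R4 (-0.30) against hid1 were not called without hid1 replicate 3 (0.144 and 0.195).

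**Figure D2:**
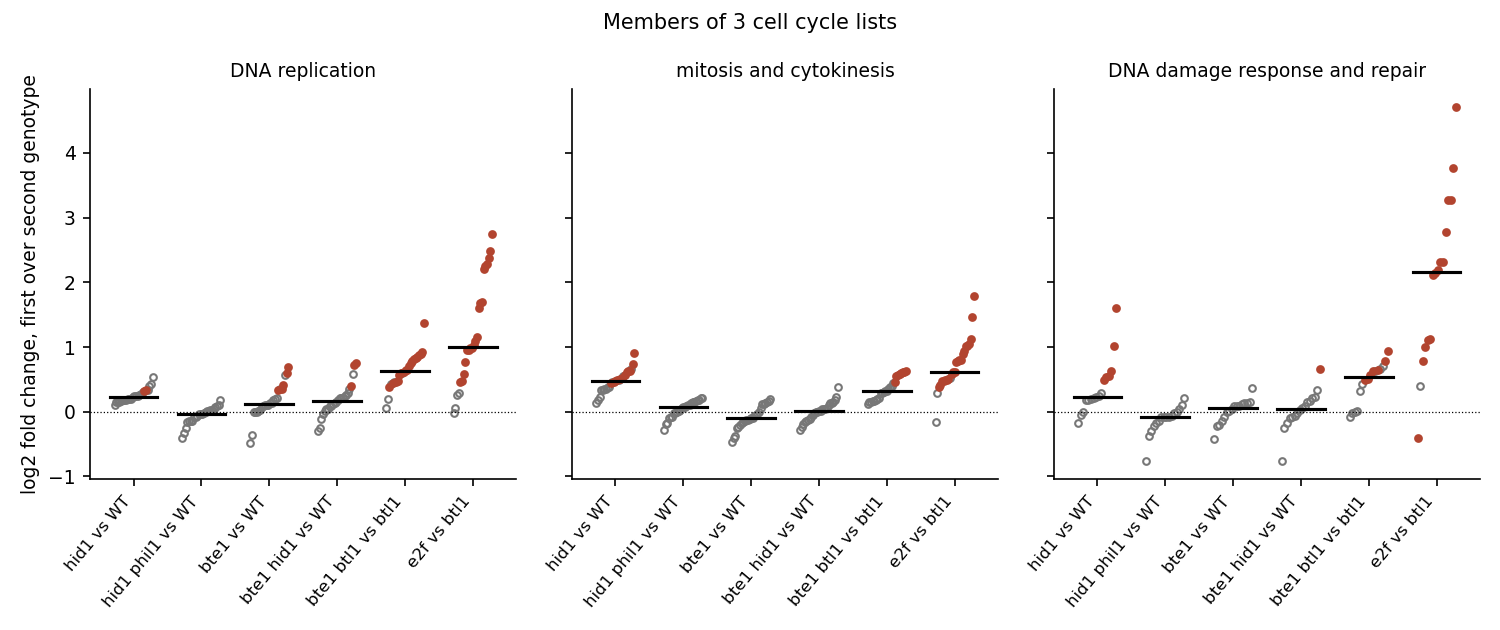
Log2 change of each measured member of the DNA replication, mitosis and DNA damage lists in 6 comparisons; filled points are called members, open points are not, and the bar is the list median. The mitosis median is 0.48 in hid1 against WT with 12 of 25 called, and the DNA damage median is 2.17 in the e2f triple mutant against btl1.

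The btl1, bte1 btl1 and e2f libraries stood apart from the other 15 in the reads of small noncoding RNA genes. The 50 tested snoRNA, tRNA and snRNA genes together had 6.77 to 10.4 CPM (here scaled by total counted reads) in these 9 libraries and 37.1 to 113 in the others. Against WT 42, 44 and 46 of the 50 were lower in btl1, bte1 btl1 and e2f, and none was called between genotypes within the 9. Of 42 miRNA genes 18, 18 and 36 were lower than in WT, and within the 9 libraries 13 were lower in e2f than in btl1 and 14 than in bte1 btl1. Comparisons of these genotypes with WT or bte1 thus cannot be told apart from a difference between library sets. Within the set of 9, bte1 btl1 is compared with btl1, and e2f is compared with btl1 mainly by its lists and counts. Most single genes of e2f are given against WT only.

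**Figure D3:**
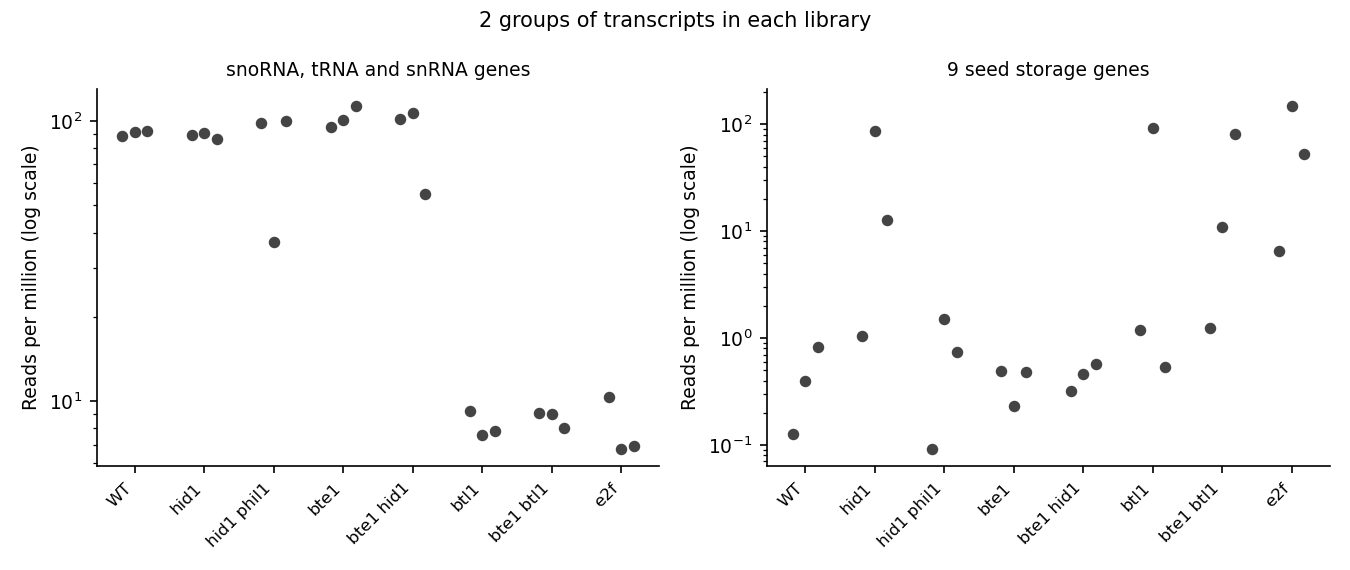
Summed CPM of the snoRNA, tRNA and snRNA genes in each of the 24 libraries by genotype, with 1 point per library. The 9 libraries of btl1, bte1 btl1 and e2f lie between 6.77 and 10.4 and the 15 others between 37.1 and 113.

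In btl1 seedlings, 3 iron-deficiency factors were among the genes with a symbol that lay most above WT. The factors BHLH100, bHLH38 and bHLH39 were higher by 3.66 (3.655), 3.65 and 2.83, and the iron transporter IRT1 by 2.04. FAMT was higher by 3.28, LEA7 by 2.95, BSU1 by 2.80 and VSP1, a jasmonate-induced storage protein, by 2.65. MIR167b was at least 24.7-fold lower, and MIR825 and TT12 were lower by ratios of 33.9 (95% counting interval 9.13 to 283) and 31.5 (8.49 to 264); RPB5E, TPS14 and MIR841a were at -4.61, -3.86 and -3.51. TCX5 (-0.35) was the 1 DREAM or E2F gene called, and its call was lost without any 1 of the 6 libraries; those of FAMT, LEA7 and MIR825 were lost without some. The jasmonate list (5 of 10, 7 adjusted over the list alone; 0.000263) and heat shock (3 of 5; 0.00784) were higher with the preset (adjusted p = 0.207 and 0.0934 with an estimated correlation). DNA replication, with 1 gene higher and 2 lower of 24, was not called (0.995). In total 1896 genes were higher and 1895 lower, and the 3791 became 2523 without btl1 replicate 1. No comparison within the set of 9 isolates btl1.

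In the btl1 background, the DNA replication and DNA damage lists rose with bte1, along with most of the genes that rose in bte1 alone. Of the 413 genes higher in bte1 against WT, 319 (77.2%) were also called higher here. Between bte1 btl1 and btl1, both in the set of 9, 19 of 24 DNA replication genes rose, 22 adjusted over the list alone (median 0.63; 1.23e-36, adjusted p = 0.00315 with an estimated correlation), such as LIG1 (0.92), CDT1A (0.85) and the helicase subunit MCM5 (0.75). Of the 16 DNA damage genes 7 rose, 9 adjusted over the list alone (median 0.54, adjusted p = 0.0394 with an estimated correlation), with BRCA1 at 0.94 and RAD54 at 0.79. TIL2, a DNA polymerase epsilon subunit, went from 0.18 to 15.5 CPM (log2 6.42, SE 0.35). HAF2 rose by 4.05, NUC-L2 by 3.24, KOM by 3.16 and the myosin XIE by 3.07. RBR1 rose by 0.50, E2FA by 0.76, ALY1 by 0.55 and E2FC by 0.49, 4 of the 23 DREAM and E2F genes (0.00229, adjusted p = 0.212 with an estimated correlation). ATX1 rose by 1.07, CMT3 by 0.79, HSP70 by 1.29, ICS1 by 0.69 and the floral repressor FLC by 1.26, while MAF5 fell by 0.96. RTL3 (-2.12), PRB1 (-2.09), TPS12 (-1.78), RLP2 (-1.61), the cold-induced KIN1 (-1.57) and ABCA8 (-1.57) fell most among genes with a symbol, at least 1 CPM and libraries that do not overlap.

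That comparison called 738 genes higher and 246 lower, with 5227 whose libraries did not overlap, where chance gives 10%. With the preset only, mitosis (8 of 25, 13 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation), histones (3 of 18; 0.431), DNA methylation (4 higher and 1 lower of 11; 0.212) and heat shock (2 of 5; 0.0684) were higher, and root cell types were lower with no member called (0.344). The root call ended without btl1 replicate 2 (0.0508). Gene calls lost without 1 library were those of E2FC (0.074 without btl1 replicate 1, 0.0522 without bte1 btl1 replicate 3), RLP2, KIN1, ABCA8, HTR2, HTR13, HTR1, HEMA1, HSP90.1 and MAF5.

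**Figure D4:**
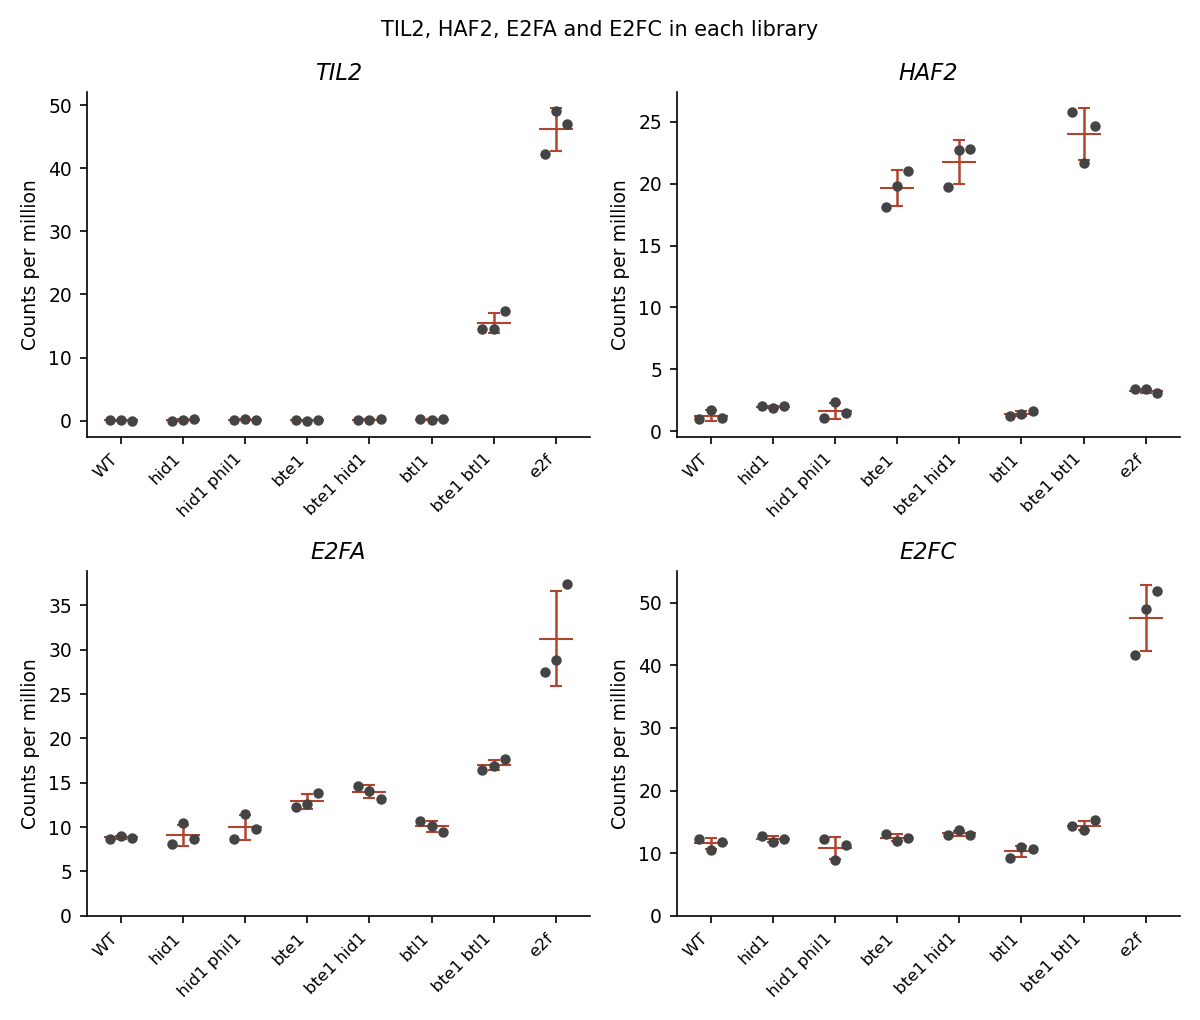
TIL2, HAF2, E2FA and E2FC in CPM for each of the 24 libraries by genotype; points are libraries, the bar is the mean and the whisker 1 SD (n = 3). TIL2 has means of 15.5 in bte1 btl1 and 46.1 in e2f, and HAF2 of 19.6 in bte1 and 24.01 in bte1 btl1.

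Against WT, bte1 btl1 had 3238 genes higher and 2923 lower, with the library sets confounded. TIL2 was higher by a ratio of 357 (95% counting interval 122 to 1735), TAT3, of the jasmonate response, by 4.84 on the log2 scale, AO4 by 4.32, HAF2 by 4.24, FAMT by 4.08 and XIE by 3.52. MIR167b and MIR825 were at least 23.3-fold and at least 21.4-fold lower; TT12 was lower by a ratio of 59.5 (10.4 to 2376), RL1 of 23.6 (7.87 to 116) and LBD26 of 19.0 (6.30 to 93.9), and RPB5E by 4.53 on the log2 scale. E2FA (0.95), RBR1 (0.48), ALY1 (0.87), ALY2 (0.30), E2FC (0.32) and DEL3 (0.50) were higher and ALY3 (-0.30) and MYB3R1 (-0.23) lower, without a call for the list of 23 (0.162). DNA replication had 18 of 24 higher, all 24 adjusted over the list alone (median 0.55; 4.71e-15, adjusted p = 0.0549 with an estimated correlation), led by LIG1 (0.94), PCNA2 (1.00) and CDT1A (0.90). Histones (11 of 18; the H3 gene HTR13 0.87, the H4 genes AT3G45930 1.03 and AT3G53730 0.95), mitosis (13 of 25; the mitotic kinases CDKB1;2 1.04, CDKB2;1 0.88 and CDKB2;2 0.90) and DNA damage (8 higher, 1 lower of 16; RAD54 1.47, BARD1 0.84) were higher with the preset only (adjusted p = 0.395, 0.378 and 0.223 with an estimated correlation). So were DNA methylation (6 higher, 2 lower of 11; CMT3 1.02, VIM1 0.82, MET1 0.39) and jasmonate (4 of 10; VSP1 2.27, JAZ5 1.71, JAZ10 0.77, adjusted p = 0.376 and 0.378 with an estimated correlation). Heat shock was higher (2 of 5; HSP70 2.08, HSP90.1 1.12; median 0.05, mean 0.53, adjusted p = 0.0142 with an estimated correlation).

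The other lists held called members in bte1 btl1 without a list call. Of 12 H3K4 methylation genes ATX1 was higher (1.05) and 4 were lower, among them ATXR3 (-0.41) and ATX4 (-0.46). SMR1 (0.68) and KRP2 (0.33) were higher and SMR2 (-0.64) lower among 10 cell cycle inhibitors; RBCS1A (0.57) was higher and PORB (-0.74) and LHCB1.3 (-0.66) lower among 22 photosynthesis genes. The light genes HY5 (0.42), BBX21 (-0.50) and PIF3 (-0.36) and the anthocyanin gene 5GT (-0.81) were called, as were ICS1 (0.61), PAD4 (0.42) and EDS1 (-0.37) in defence (list median -0.03, mean 0.07, test pointing up, 0.841). MAF5 (-1.36), MAF4 (-0.83) and MAF1 (-0.32) were lower, ELF4 was higher (0.76) and ELF3 (-0.42) and TOC1 (-0.39) lower in the clock, IRT1 was higher (1.58) and PHT1;1 (-0.67) and PRP3 (-0.55) lower in the root list, and CLV1 (-0.56) and STM (-0.57) were lower in the meristem list. The storage protein gene SESA2 was at least 108.5-fold higher as 1 of 12 seed genes, and its call was lost without bte1 btl1 replicate 3 (0.785). Calls were also lost without single libraries for E2FC (0.123 without WT replicate 2), DEL3 (0.112 without WT replicate 3), ALY3 (0.0575 without WT replicate 2), MYB3R1 (0.108 without WT replicate 2), KRP2, PIF3, 5GT, PAD4, JAZ10, TOC1, PRP3 and STM, and for the DNA methylation list without WT replicate 2 (0.085) and 3 (0.0566) and bte1 btl1 replicate 1 (0.0516) and 3 (0.0827). Against bte1, also across the sets, bte1 btl1 had 2337 genes higher and 2096 lower, with TIL2 at 7.34 and 18 of 24 DNA replication genes higher (4.07e-11, adjusted p = 0.114 with an estimated correlation). The histone, mitosis, DNA damage, DNA methylation and jasmonate lists were higher there with the preset only (adjusted p = 0.547, 0.175, 0.175, 0.223 and 0.378 with an estimated correlation), and the calls of DNA methylation and jasmonate ended without bte1 replicate 2 (0.0528) and without bte1 btl1 replicate 3 (0.0564).

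In the e2f triple mutant the DNA damage, DNA replication, DNA methylation and DREAM and E2F genes were raised. BRCA1 rose from 9.54 to 99.3 CPM (log2 3.38, SE 0.11, adjusted p = 6.73e-17), RPA1E by 3.59 (3.585) and RAD54 by 2.80. The ribonucleotide reductase subunit TSO2 rose by 2.83 (2.825), the licensing factor CDC6 by 2.77 (2.765) and the MCM helicase subunit PRL by 1.42. CMT3 rose by 2.61, the chromatin remodeler DDM1 by 1.57 and MET1 by 1.28. In the DREAM and E2F family DEL3 (3.26), SOL1 (2.43), E2FC (2.04), E2FA (1.82), RBR1 (1.49) and ALY1 (1.25) were higher, as were DEL1 (0.87), TCX8 (1.19), TCX6 (0.72), MYB3R4 (0.59), DPA (0.57), ALY3 (0.56), TCX5 (0.54) and ALY2 (0.37). TCX7 (-2.97), MYB3R3 (-0.52) and MYB3R5 (-0.47) were lower, and E2FB (-0.31, adjusted p = 0.0636), DEL2 (0.37), MSI1 (0.19), DPB (0.14), TSO1 (0.09) and MYB3R1 (0.05) were not called. HIL1 was higher by 1.495. Among the genes with a symbol and the largest changes LTP4 and DRP4C were at least 492-fold and at least 47.7-fold higher, TIL2 had a ratio of 1060 (95% counting interval 362 to 5143), and CSLG2 of 277 (49.3 to 10980), and NATA1 was at 8.08 on the log2 scale. The storage protein CRU3 had a ratio of 2011 (361 to 79470), but was at 1.42, 67.3 and 18.05 CPM in e2f replicates 1, 2 and 3, so most of it came from the library with the highest seed storage reads. MIR841a was at least 23.5-fold lower, and MIR167b and MIR825 had ratios of 108 (19.0 to 4303) and 98.4 (17.3 to 3922) below WT. RPB5E (-5.52), PAP14 (-5.01) and the H2A gene HTA4 (-4.95) were lower. MIR167b had 0 reads in btl1 and in bte1 btl1, and MIR825 had 2 and 0, so their falls were not particular to e2f. MIR841a and RPB5E were also among the genes lower in btl1 than in WT.

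List tests in the e2f mutant against WT had counterparts against btl1, within the set of 9. DNA damage had 15 of 16 higher and 1 lower (median 2.13; 4.58e-28, adjusted p = 0.000207 with an estimated correlation) and, against btl1, 14 higher and 1 lower (median 2.17, adjusted p = 5.24e-05 with an estimated correlation). DNA replication had 22 of 24 higher, also 22 adjusted over the list alone (median 1.02, adjusted p = 0.0189 with an estimated correlation), and 20 against btl1 (median 1.01, adjusted p = 0.00669 with an estimated correlation). DNA methylation had 8 of 11 higher and 2 lower in both comparisons (medians 1.28 and 1.29, adjusted p = 0.00495 and 0.00202 with an estimated correlation). Of the DREAM and E2F list 14 of 23 were higher and 3 lower, and against btl1 16 and 3 (medians 0.56 and 0.76, adjusted p = 0.04 and 0.0095 with an estimated correlation). The 14 include E2FA and E2FC, which per the labels are mutated in this genotype, and the list was not tested without the mutated genes. The mitosis list, with 24 of 25 members higher (CDKB1;1 2.08, AUR1 1.55, CDKB1;2 1.56), was called with the preset only, and 22 were higher against btl1 (adjusted p = 0.248 and 0.204 with an estimated correlation). Histones (13 of 18; HTR2 1.29, HTR1 0.95, the H4 gene AT1G07820 0.64), salicylic acid (12 of 13; SARD1 2.67, WRKY70 2.64, CBP60G 1.59) and jasmonate (8 of 10; VSP1 3.38, JAZ5 3.25, JAZ1 1.79) were higher with the preset only (adjusted p = 0.442, 0.177 and 0.175 with an estimated correlation; 0.509, 0.109 and 0.334 against btl1). Photosynthesis (18 of 22 lower; LHCA1 -1.58, LHCB1.3 -1.45, LHCA3 -1.15) and the clock (7 of 12 lower; PRR9 -2.05, GI -1.001, RVE8 -0.70) were lower with the preset only (adjusted p = 0.344 and 0.31 with an estimated correlation; 0.252 and 0.221 against btl1). Other splits of the 6 e2f and WT libraries gave up to 10 list calls, as many as the real one.

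The lists without a call in e2f held members that changed both ways. ATX1 was higher (1.40) and ATX5 (-0.50) and WDR5A, an H3K4 methylation adaptor, lower (-0.63) among 12 H3K4 methylation genes; WDR5A went from 5.28 to 3.41 CPM, was not called against btl1 and lost its call without WT replicate 1 (0.0702) and e2f replicate 2 (0.083). KRP3 (1.71), KRP6 (1.45) and KRP4 (0.37) were higher among cyclin-dependent kinase inhibitors. PIF3 was higher (0.75) and HFR1 (-1.95) and PIF4 (-1.19) lower among 17 light genes, a list with a median of -0.09, a mean of 0.02 and a test pointing down (0.698). The anthocyanin genes DFR (2.51), UF3GT (2.07) and LDOX (1.72) were 3 of 11 higher, and HSP18.2 (1.82), HSFA2 (1.51) and HSP90.1 (0.87) 3 of 5 in the heat shock list. The floral repressors FLC (-2.72), MAF4 (-2.34) and MAF1 (-0.69) were lower, and FLC was at -2.02 against btl1. NRT2.1 was higher (3.72) and PRP3 (-0.51) and CASP2 (-0.50) lower in the root list (median -0.04, mean 0.28, test pointing down, 0.903), and CUC3 (-1.77), KNAT1 (-0.72) and CLV1 (-0.69) were lower in the meristem list. Of 12 seed maturation genes 5 were higher, 2 adjusted over the list alone, among them CRA1 (6.49), OLEO1 (4.59) and FUS3 (2.11), while storage reads ran from 6.54 to 147.5 CPM over the 3 e2f libraries. CRU3, OLEO1, TCX8, MYB3R5, PRP3 and CASP2 lost their calls without 1 or more libraries.

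Against WT the e2f mutant had 5776 genes higher and 5653 lower, and against btl1 5787 and 5429; 4493 and 3769 were called alike in both and 39 and 43 in opposite directions. Libraries of e2f and WT did not overlap for 11891 genes, where chance gives 10%. The e2f replicates had the widest spread of counts of any genotype, up to 34.38 as chi-square per degree of freedom. Genes called against WT in both bte1 btl1 and e2f in the same direction were 1362 higher and 1502 lower, with 920 in opposite directions. Independent lists would share 854 and 755. Simulated genotypes without a change shared 0, which cannot show what shared libraries add among changed genes. The covariance of the log2 changes was 0.54 against 0.025 in simulations with shared WT libraries. Part of the excess may come from the shared WT libraries and from the shared library set. Both were also compared with btl1 in place of WT, so that they share the btl1 libraries. Then 393 genes were higher and 129 lower in both (522), and 160 went in opposite directions. Independent lists would share 195 and 61.0. Simulated genotypes without a change again shared 0, with the same limit. The covariance was 0.116 against 0.0297 simulated. The 3 WT libraries cannot be halved to give each comparison its own.

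Tests of non-additivity asked whether the effect of bte1 differed between backgrounds. The effect differed between the WT and hid1 backgrounds for 75 genes, 49 with a positive and 26 with a negative difference. Among them were ARF10 (1.04, adjusted p = 0.000156), CPK9 (0.97), UGT85A2 (1.45), GMI1 (-1.09) and NUC-L2 (-2.03), the last at 16.3 CPM in bte1 hid1 and 9.92 in hid1. The count was 27 without WT replicate 3, 47 without hid1 replicate 2, 35 without hid1 replicate 3, 35 without bte1 hid1 replicate 1, 33 without bte1 replicate 1 and 37 without bte1 replicate 3. Between the WT and btl1 backgrounds 15 genes differed, 10 up and 5 down, with each change with bte1 taken within 1 library set: ZYP1a (2.19, adjusted p = 0.00359), BRCA1 (1.15), MAP65-4 (0.92), DEG8 (0.80) and RHS19 (-1.13). It ranged from 6 to 16 when 1 library was left out and moved by over 1.5 times for 10 of the 12 libraries, down to 6 without WT replicate 1; the calls of MAP65-4, DEG8 and RHS19 were lost in some of these fits. TIL2 was not called for this difference (5.48, SE 1.58, adjusted p = 0.32).

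**Figure D5:**
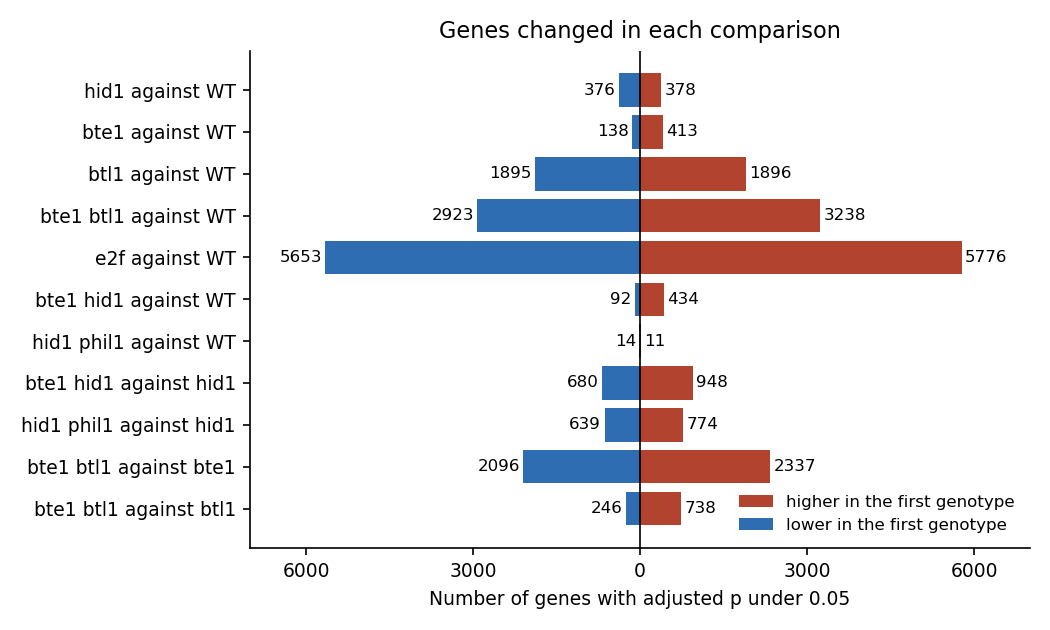
Number of genes called higher and lower in each comparison (adjusted p at the 0.05 threshold; 3 libraries per genotype). The e2f mutant against WT has 5776 higher and 5653 lower genes and hid1 phil1 against WT 11 and 14.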

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

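The tests of the opposed hid1 genes, of the overlap of bte1 btl1 with e2f, of the 15 genes below and of the 12 other seed genes were set before their results were seen; the 3 patterns that are weighed, and all other counts over regroupings of the libraries, were chosen after. The list results of non-additivity that are named here were picked after seeing which held with an estimated correlation.

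The log2 change with bte1 differed between the WT and hid1 backgrounds for 75 genes (a test of the difference itself). Over 100 drawn regroupings of the 12 libraries 4 gave as many genes, the real one included. The highest of the others gave 361, which points to a structure of the samples. The regroupings mix genotypes that differ from each other, so they cannot exclude chance for this difference. In the same comparison 10 lists were called with the preset correlation and 2 held with the estimate: DNA damage response, with a median difference of -0.27 (adjusted p = 0.0393 with an estimated correlation), and flowering time, with 0.40 (adjusted p = 0.015 with an estimated correlation).

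Between the WT and btl1 backgrounds the change with bte1 differed for 15 genes by the same kind of test. Of 100 drawn regroupings 11 gave as many and the highest gave 1679, so chance cannot be excluded and the samples have a structure of their own, the 2 library sets among them. Of 10 lists called, 5 held with the estimate: DNA replication (median 0.43), mitosis (0.45), DNA damage response (0.37), heat shock (-0.41) and root cell types (-0.40), with adjusted p of 0.0129, 0.015, 0.015, 0.015 and 0.0447.

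The 9 libraries of btl1, bte1 btl1 and e2f had few snoRNA, tRNA and snRNA reads. Library depth is argued against as the source: the highest e2f library had 10.4 CPM of them at a depth like that of the other genotypes, whose lowest library had 37.1. A difference in preparation or processing between the library sets and an effect of the btl1 and e2f mutations cannot be told apart. Between e2f and btl1 0 of the 50 genes were called by edgeR, as a difference between sets would give, and each of the 3 genotypes had at least 42 of them lower than WT, as a mutation effect would give. No genotype was in both sets, which keeps both open. The FPKM values of the sets did differ in processing: assembled loci have values in the 15 other libraries and none in these 9. In the counts, AT2G35743 followed HIL1 in the 15 and lay below it in the 9. The counting tool was not stated, so whether the counts were also processed apart is not known, and a mutation effect is not excluded.

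In hid1 phil1 replicate 2, HID1 had 9 reads where the other replicates had none. A small share of RNA or reads from plants with HID1 is a candidate explanation: over 5 genes that are near silent in the other replicates, the pooled share of the WT level was 4.51%. They stand for 2 loci and not 5 separate checks: HID1 (4.56%, 95% counting interval 2.09% to 8.66%) with its neighbours AT2G35744 (4.91%), AT2G35750 (3.90%) and AT2G35747 (1.499%), and MRD1 (5.23%, 3.64% to 7.28%), which gave 35 of the reads. A share of that size is argued against as the source of this library's lower small RNA reads, which lay 62.2% below the lower of the other hid1 phil1 replicates. No biological explanation was tested.

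Seed storage transcripts were high in single libraries: 87.0 CPM in hid1 replicate 2, 92.5 in btl1 replicate 2, 81.5 in bte1 btl1 replicate 3 and 147.5 and 53.0 in e2f replicates 2 and 3, against at most 0.83 in WT. A steady effect of genotype is argued against as the source of these high libraries: the highest library exceeded the lowest by 83.5 times in hid1, 174.6 in btl1, 65.8 in bte1 btl1 and 22.6 in e2f, and in each genotype 0% of at least 5126 genes with a like number of reads differed as much. Seeds or embryos among the seedlings may be the source: of 12 seed genes outside the 9 storage genes at least 10 lay above every WT library in each of these 5 libraries, against at most 4 in a bte1 or bte1 hid1 library. Other libraries of the same genotypes had 3 to 10, among them btl1 replicate 3 with 6 at a storage level within that of WT, so a count of 6 does not need seeds. The summed reads of the 12 were at 37.0 CPM in hid1 replicate 2, 29.2 in btl1 replicate 2, 41.7 in bte1 btl1 replicate 3 and 29.8 and 25.5 in e2f replicates 2 and 3, against at most 7.56, 10.7, 11.3 and 15.2 in the other libraries of these genotypes. A lower level from genotype beneath the high libraries cannot be told apart from seeds: in 3 of the 4 genotypes the lowest library, at 1.04 in hid1, 1.24 in bte1 btl1 and 6.54 in e2f, was above WT as well, which either would give, and in btl1 it was not (0.53). An effect of genotype that varies between samples was not tested.

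For the pairwise gene counts the 6 libraries allow 10 splits, too few for a share under 0.05. In each comparison 1 of the 10, the real one, gave as many genes. The real count and the highest other were 754 and 4 in hid1, 551 and 0 in bte1, 3791 and 0 in btl1, 6161 and 1 in bte1 btl1, 11429 and 0 in e2f, 526 and 0 in bte1 hid1 and 25 and 0 in hid1 phil1, each against WT. They were 1628 and 1 for bte1 hid1 against hid1, 1413 and 0 for hid1 phil1 against hid1, 4433 and 0 for bte1 btl1 against bte1 and 984 and 0 for bte1 btl1 against btl1.

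For the counts of list calls with the preset correlation the splits were again 10 per comparison, too few for a share under 0.05. Here each comparison's 19 lists were adjusted on their own, so the real counts differ from those over 209 tests for bte1 hid1 against WT (4 and 6) and against hid1 (9 and 8). Against WT the real count, the highest other and the number of splits with as many were 9, 10 and 2 in hid1, 6, 9 and 2 in bte1, 2, 6 and 8 in btl1, 7, 8 and 4 in bte1 btl1, 10, 10 and 4 in e2f, 4, 12 and 4 in bte1 hid1 and 3, 6 and 7 in hid1 phil1. They were 9, 8 and 1 for bte1 hid1 against hid1, 5, 7 and 6 for hid1 phil1 against hid1, 6, 8 and 7 for bte1 btl1 against bte1 and 8, 10 and 4 for bte1 btl1 against btl1.

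For the genes called alike in bte1 btl1 and e2f, 3 of 100 regroupings gave as many, the real one included. The real value was 2864 and the highest other 8098, from a regrouping with the e2f libraries in the place of WT, which is a structure of the samples. For the opposed hid1 genes, 1 of 100 regroupings, the real one, gave as many in each case. The counts were 391 in bte1 hid1 with a highest other of 319, and 481 in hid1 phil1 with a highest other of 15. All these regroupings mix genotypes that differ from each other. A small share therefore speaks only against no difference among the genotypes, and chance cannot be excluded for the overlap or the opposed genes from it.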

How the results depend on the processing

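The settings with protein-coding genes only, with a fit within 1 library set and with btl1 or bte1 btl1 in place of WT were chosen after the data were seen. Of 713 named gene results, 530 kept their side of the threshold in every alternative run for them and every fit with 1 library left out. Where either fit called the gene, its direction was kept too. A change of sign in a result called in neither fit counts here as kept. DESeq2 kept 704, RLE factors 712 and no filter 699. Only the genotypes compared kept 645 of the 696 it was run for (45 lost their call), and FPKM with 1 added 344 of 380 (36 lost it). The fit within 1 library set kept 357 of 373 (16 lost it). Of 89 e2f results, btl1 in place of WT kept 76, with 11 calls lost and 2 gained. With bte1 btl1 in place of WT 73 were kept, 10 lost their call, 3 gained one and 3 reversed. Size factors by RLE moved the median of all genes by at most 0.00889 on the log2 scale. Of 70 list calls 13 held with an estimated correlation, 55 with fry, which asks a different question, and 67 with RLE factors.

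For the counts below the cause was not tested, except that a fit within 1 set or on the compared genotypes has fewer libraries and another spread. With only the genotypes compared, bte1 against WT had 874 genes, hid1 phil1 against hid1 651, and non-additivity 356 for bte1 with hid1 and 27 for bte1 with btl1. DESeq2 gave 50 for hid1 phil1 against WT and 236 and 51 for the tests of non-additivity. With protein-coding genes only, which tests fewer genes, hid1 phil1 against WT had 15. For bte1 btl1 against btl1, FPKM gave 464 with 1 added and 441 with 0.1 added, and the fit within the set 647. For bte1 with hid1, FPKM with 1 added gave 165 and the fit within the set 158. With both against btl1 in place of WT, 522 genes were called alike in bte1 btl1 and e2f.

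Against bte1 btl1 in place of WT, e2f had HIL1 at -1.79, HSP90.1 at -0.24 and PRP3 at 0.0388, each the reverse of its sign against WT; HIL1 is itself high in bte1 btl1 (7.99 CPM), and the cause was not tested for the others. Sign changes of 71 gene results called in neither fit, and 3 with both genotypes at or under 3 reads, were left out of this by a rule set after they were seen.

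Leaving out 1 library, which leaves 2 in its group, gave 349 to 623 genes for hid1, 334 to 431 for bte1, 2523 to 3056 for btl1, 4357 to 5411 for bte1 btl1, 9987 to 11447 for e2f, 353 to 398 for bte1 hid1 and 18 to 34 for hid1 phil1 against WT. It gave 814 to 1161 and 460 to 1385 for bte1 hid1 and hid1 phil1 against hid1, 27 to 79 and 6 to 16 for the tests of non-additivity, 159 to 319 and 198 to 420 for the opposed genes, and 66 to 72 list calls. The lowest value for hid1, for both doubles against hid1 and for both opposed counts came without hid1 replicate 3. In these fits 145 named gene results lost their call at least once and 20 list calls did.

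Replicate numbers do not pair the samples: same-number correlations of deviations over the 28 genotype pairs ran from -0.312 to 0.244, and in 0 pairs were all over 0.1. With a replicate block hid1 against WT had 769 genes, bte1 508 and the lists 69 calls, and no count moved by over 1.5 times; 6 named gene calls and 3 list calls were lost.

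FPKM fits across the library sets were not run, since the values of the sets cover different features. Depth limits genes near the floor, above all in the 6 libraries of btl1 and bte1 btl1.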

Other observations

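The tests of the bte1 genes and of the overlap of hid1 with e2f below were chosen after the genes had been seen.

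A group of genes rose with bte1 in each background. In the comparisons of bte1 with WT, bte1 hid1 with hid1 and bte1 btl1 with btl1, which share no library, 232 genes were higher in all 3, where independent lists would share 0.603, and 25 were lower (0.0482). They include HAF2, TAF4B and NUC-L2, named in the comparisons, and ABCA7 (1.86 in bte1 against WT), AAS (1.83) and PAI1, of tryptophan synthesis (1.79), which were picked after their values were seen. A response to bte1 in each of these backgrounds may account for the 232, though its size differed between the WT and hid1 backgrounds for 3 of them by the test of non-additivity (NUC-L2 -2.03, HIL1 -1.095 and AT5G25230 -1.514, the last picked after its value was seen). Some of the 232 are pairs of entries with the same values, such as AT5G15950 and AT5G15948 (each at 61.4 CPM in WT and 96.5 in bte1). The 232 are therefore not all separate changes. The figures for independent lists also take each tested gene as equally likely to be called. Of the 232, 89 were also higher and 59 lower in e2f against btl1, where independent lists would share 61.3 and 57.5. That comparison shares the btl1 libraries with bte1 btl1 against btl1, so part of the excess of the 89 may come from them.

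Of the genes higher in hid1 against WT 202 were also higher in e2f against btl1, and 141 were lower in both, where independent lists would share 99.9 and 93.2. These comparisons share no library, so the excess of the 202 does not come from shared WT libraries, and raised cell cycle and DNA damage genes in both mutants are a candidate explanation that was not tested apart from the lists. For bte1 the like counts were 164 and 48 against 109 and 34.2.

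Entries whose identifier ends in a transcript number, many of them transposon genes, were higher in hid1 for 16 and lower for 4 of 192 tested, and in bte1 for 2 and 7. AT2G41640 was below WT (34.97 CPM) in hid1, bte1, both doubles with hid1, btl1 and bte1 btl1, and at 28.5 CPM in e2f. The first principal component held 40.8% and the second 16.9% of the variance of the 24 libraries.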
